A study of Mus musculus with 2 samples.

How the data were processed

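H3K27ac ChIP-seq libraries were made from liver of E16.5 mouse embryos of strain B6NCrl, 1 library for each of 2 biological replicates, each a pool of male and female embryos. Per the labels, libraries were size-selected and the assembly was mm10. The authors' peak lists were used as deposited, in the 10-column narrowPeak layout. These were a list for each replicate, a list called on both replicates together, and the subset of the latter that the authors kept as replicated. Per the accompanying descriptions of the files, the replicated list derives from the other 3 lists, and the rule was not stated. The aligner, the peak caller and its thresholds were not given in the sources used here. The deposited peaks give an enrichment ratio for each peak, and what it is relative to was not stated. They also give, by the authors, the −log10 p and −log10 q of each peak. The lowest −log10 p was 2.0008 in replicate 1, 2.0071 in replicate 2 and 2.0542 in the pooled and replicated lists, while q-values of 0.01 or lower covered 80.6%, 77.1%, 86.3% and 89.7% of the peaks. Read counts and depth were not part of the lists, so the depth of each library is unknown and no interval for a peak's value was computed.

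Peaks were analysed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9. The mouse genome sequence of the same assembly and its GENCODE annotation of protein-coding genes were used. Peaks on unplaced or unlocalised contigs (7, 6, 4 and 4 in the lists of replicate 1, replicate 2, pooled and replicated peaks) were left out of the comparisons and 1 of them is described in the closing section. Libraries that the labels name as possible controls were not analysed here. Genes matched by symbol, with 0 of the listed symbols left unmatched.

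Both libraries formed 1 group, so no groups were compared. Peaks were called overlapping when they shared at least 1 bp. Random expectations came from 100 seeded placements of the peaks within their chromosomes. A peak was assigned by its centre to a promoter (within 1 kb of any protein-coding TSS), else to an exon, an intron or intergenic sequence. A gene had a promoter peak when a replicated peak lay within 1 kb of any of its annotated TSS. Its promoter enrichment was the highest ratio among such peaks in each replicate list, and the 2 values were averaged. A peak that reached into this 1 kb counted with the ratio of the whole peak, which may stem from signal farther away. Enrichment ratios of different lists were not rescaled.

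A set of 23 gene lists (555 memberships, with 7 genes in more than 1 list), 20 motifs, the tests and the rule for naming genes were fixed before the data were examined. Lists were compared with all other coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 23 lists at a threshold of 0.05. Breadth was the number of bases covered by replicated peaks within 5 kb of the TSS, for list members with a promoter peak, tested against 10000 random lists of equal size by a two-sided permutation test over 19 lists with at least 3 such members. Replicate differences were medians of the log2 ratio of promoter enrichment, placed among 10000 random lists matched on enrichment in 10 bins, with no test. Clusters were replicated peaks joined over gaps of at most 10 kb, and genes with a TSS inside the 500 clusters with most covered bases were tested by Fisher's exact test. Motifs were searched as consensus letters on both strands in 500 bp windows at the centres of distal peaks, over 1 kb from any TSS. Each window had 1 control window on the same chromosome with GC content within 1 percentage point and at least 5 kb from any peak, which was found for 35884 of 35885 windows. Each motif written backwards, without complementing, served as a control of base content. It does not keep the pairs of neighbouring bases, and some motifs gain a CG pair when written backwards. A comparison of each motif with its backwards form, by Fisher's exact test on the hits in peaks and in controls, was added after the values were seen.

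For each list, the named genes were the 3 members with the highest mean promoter enrichment and up to 2 members, in alphabetical order, with no promoter peak in any of the 4 peak lists. The 25 clusters with most covered bases and the 5 genes with the largest promoter ratio in each direction between replicates were also named, and all motifs were reported. Afp, Alb and 7 globin genes of the closing section were named after their values were seen.

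The tests were tested on simulated data with known changes. Of 20 simulated lists of 25 genes with a promoter peak in 85% of members, 19 were called, and 0 of 80 unchanged lists were. Of 20 lists with 2 times the covered bases, 16 were called, and 0 of 80 unchanged lists were. All 10 motifs placed into 5% of 8000 windows were called, and 0 of the 20 motifs were called in windows with none placed. These windows and their controls were both drawn from dinucleotide frequencies, unlike the genomic controls of the main test. A peak list with copied peaks gave an overlap of 60.6%, against 60.6% from its construction.

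A total of 45 alternatives were fixed before the data were examined, and 3 were added afterwards. They covered the overlap that counts as shared, a q-value limit of 0.01, the 20000 strongest peaks, promoter widths of 500 and 2500 bp, 1 TSS per gene, the pooled list, a background matched on GC content, breadth within 10 kb, cluster gaps of 5 and 20 kb, ranking by signal, motif windows of 1000 bp, controls drawn from dinucleotide frequencies, other measures of the replicate difference, and each replicate alone. Those added were restriction to genes with mostly single-copy promoters, and 2 variants of the comparison of erythroid with hepatocyte genes. Copies of a promoter were counted as the share of 32-base words, taken every 20 bases within 1 kb of the TSS, with another exact match in the assembly on either strand. The comparison of erythroid with hepatocyte genes used the 4 erythroid lists (transcription factors, globins, heme and iron, red cell membrane) and the 4 hepatocyte lists (secreted proteins, transcription factors, P450 and bile acid, urea cycle), with 100000 permutations of the group labels.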

Results

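Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by ChIP-seq in the liver of mouse embryos at embryonic day 16.5 (E16.5). At this stage the liver is the main site of blood formation as well as a developing metabolic organ. The study held 1 group, E16.5 liver of strain B6NCrl, with 2 biological replicates. Each replicate was a pool of male and female embryos. The pool of replicate 2 came from 41 embryos, and the number for replicate 1 was not given. The authors' peak lists on the mouse assembly mm10 were used, with 80847 peaks for replicate 1 and 79816 for replicate 2. A list called on both replicates together (pooled) held 56396 peaks, and its subset that the authors kept as replicated held 52393. The peaks covered 46.4 Mb in replicate 1, 42.4 Mb in replicate 2 and 36.5 Mb in the replicated list. Median peak width was 329 bp in replicate 1, 316 bp in replicate 2 and 429 bp in the replicated list. The depth of the libraries was unknown, because the lists give no read counts. Each peak carried the authors' enrichment ratio, used here to rank and describe peaks. Values per gene below are the mean ± SD of that ratio for the strongest peak within 1 kb of a transcription start site (TSS) in each replicate, n = 2. Tests over gene lists treat genes as units, so their p-values describe these 2 pools and not a population of embryos.

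The first comparison asked how far the replicates shared their peaks. Of the replicate 1 peaks, 64.2% overlapped a replicate 2 peak, and of the replicate 2 peaks, 69.3% overlapped a replicate 1 peak. Random placement of the second list within each chromosome gave 3.67% ± 0.0760 and 3.25% ± 0.0669 (SD, 100 placements). The bases covered in both made up 57.3% of the bases covered in either, against 0.962% ± 0.0268 at random. Sharing depended on peak strength. With peaks divided by enrichment into 10 classes of equal size, all peaks of the highest class were shared, but only 36.3% of the lowest class of replicate 1 and 44.4% of the lowest class of replicate 2. Peaks found in replicate 1 alone had a median enrichment of 3.10, against 4.55 for its shared peaks, and those found in replicate 2 alone had 3.05 against 4.27. Over 51881 overlapping pairs, enrichment correlated between replicates with a Spearman rho of 0.718 and, on the log2 scale, a Pearson r of 0.827. These correlations are across peaks, which are not independent replicates, so no p-value is given.

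**Figure D1:**
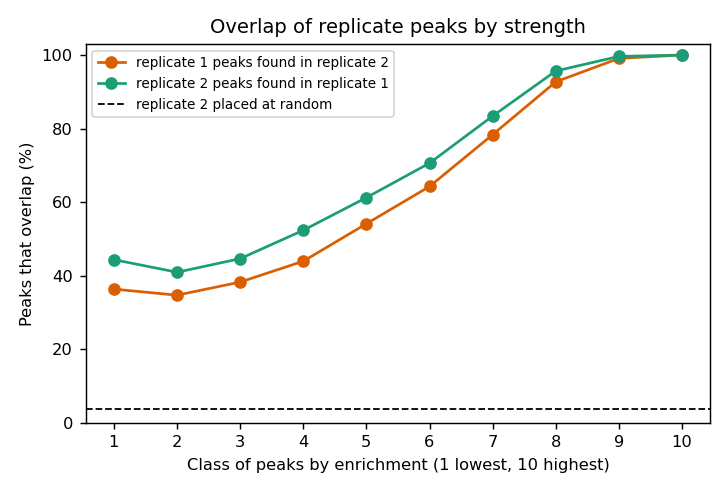
Percent of peaks that overlap a peak of the other replicate (y axis) in 10 classes of peaks by enrichment, from lowest to highest (x axis), for replicate 1 (orange) and replicate 2 (green). Overlap reached 100% in the highest class of both replicates, and the dashed line marks the 3.67% obtained with random placement.

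Most of the pooled peaks were kept in the replicated list, 92.9% of those on the main chromosomes. The 4003 peaks not kept were weak and narrow, with a median enrichment of 2.86 and a median width of 212 bp, against 4.28 and 429 bp for those kept. Of the kept peaks, 48010 overlapped a peak in both replicate lists. A further 2866 overlapped a peak in replicate 1 only, 1506 in replicate 2 only and 7 in neither. Overlap of 1 bp in both replicate lists was therefore not the rule the authors applied.

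Acetylation was concentrated at promoters. Of the replicated peaks, 28% had their centre within 1 kb of a protein-coding TSS, 12.5 times the 2.24% ± 0.0692 found with random placement (SD, 100 placements). In the separate replicate lists the promoter share was 21.1% ± 0.560 (SD, n = 2), so it was lower there than in the replicated list by more than the spread between replicates. Introns held 46.5% of replicated peaks (43.4% at random), exons 4.93% (3.73%) and intergenic sequence 20.6% (50.6%). Promoter peaks were stronger and wider than the rest, with a median enrichment of 6.44 and width of 625 bp, against 3.91 and 378 bp. Of 21827 protein-coding genes, 10521 (48.2%) had a replicated promoter peak, and their median promoter enrichment was 9.61 among those with a peak in both replicates. Chromosome 11 had the most replicated peaks per Mb (34.8), followed by chromosome 19 (32.6). Among the autosomes, chromosome 14 had the fewest (14.5), and chromosome X had 5.30.

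Promoters of red cell genes were acetylated almost without exception. Gene lists for cell types and functions were fixed before the data were examined, and the share of each list with a replicated promoter peak was compared with all other coding genes. All 17 genes listed as erythroid transcription factors had a promoter peak (95% interval 80.5% to 100%, adjusted p = 1.17e-05, two-sided Fisher's exact test, Benjamini-Hochberg over 23 lists). So did all 25 genes of the red cell membrane and cytoskeleton (adjusted p = 9.01e-08, Fisher's exact test) and all 10 globin genes (adjusted p = 0.00112, Fisher's exact test). The 10 globin genes lie at 2 loci on chromosomes 7 and 11, so they are not 10 independent observations. Among genes of heme synthesis and erythroid iron uptake, 19 of 20 had one (95%, adjusted p = 3.11e-05, Fisher's exact test). Intervals are Clopper-Pearson and cover counting error only.

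The highest promoter enrichments in these lists were at genes of the red cell membrane and of heme synthesis. Trim58, a ubiquitin ligase of maturing red cells, had 41.2 ± 4.12 (chromosome 11, peak 58639421 to 58643523), Epb42, which anchors the membrane skeleton, 40.9 ± 4.64, and Trim10 40.7 ± 7.26. The heme enzyme genes Hmbs (chromosome 9, peak 44339995 to 44345344) and Ppox had 37.7 ± 1.54 and 37.7 ± 4.81, and Cpox had 30.7 ± 5.09. Klf1, the activator of the adult globin programme, had 33.6 ± 7.90 under a peak of chromosome 8 from 84899631 to 84904053, Nfe2 32.9 ± 6.44 and Zbtb7a 31.4 ± 5.41. Among globin genes, Hbb-bs had 32.2 ± 3.30, Hba-a2 26.6 ± 6.14 and Hba-a1 24.3 ± 4.24. Hba-a1 and Hba-a2 are near-identical copies, with another exact copy for 74.7% and 79.8% of the 32-base words around their TSS, so the division of signal between them is uncertain. Hbb-bs shares 44.4% of its words with another site. The 1 gene without a promoter peak was Slc25a37, the mitochondrial iron importer, for which all promoter words (100%) had another copy in the assembly.

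Hepatocyte genes were also acetylated more often than other genes, but at lower enrichment. Of 35 genes for proteins secreted by fetal hepatocytes, 29 had a promoter peak (82.9%, adjusted p = 6.00e-05, Fisher's exact test), as did 20 of 24 hepatocyte transcription factors (83.3%, adjusted p = 0.00112, Fisher's exact test). The retinol carrier gene Rbp4 had 20.3 ± 2.36 (chromosome 19, peak 38124935 to 38125387), the fetuin gene Ahsg 13.1 ± 1.55 and Itih1 10.8 ± 1.05. Among the factors, Atf5 had 21.2 ± 2.93 (chromosome 7, peak 44815027 to 44818208), Cebpb 12.3 ± 1.14 and Cebpa 11.5 ± 3.14. F9, Serpina1e, Creb3l3 and Hlf had no promoter peak in any of the 4 lists, and 30.3% of the words at Serpina1e had another copy. Within 5 kb of the TSS, however, 1800 bp were covered at Creb3l3 and 1255 bp at Hlf (0 bp at F9 and Serpina1e). Median promoter enrichment was 6.38 in the secreted list and 6.78 in the factor list, against 21.8, 25.9 and 22.3 in the lists of erythroid factors, heme genes and red cell membrane genes. The globin list had a median of 11.5, near the housekeeping median of 11.6. Pooled into 2 groups after the values were seen, erythroid genes with a promoter peak had a median enrichment of 23.9 (71 genes) and hepatocyte genes 6.10 (75 genes), a 3.92-fold difference. The p-value of a permutation test on this difference is not given, since the list medians had been seen when the groups were formed. The hepatocyte group included the adult and metabolic lists described next. Peaks counted with the ratio of the whole peak, and erythroid genes had more bases covered within 5 kb of the TSS (median 6329 against 1843 bp). Breadth and enrichment are therefore not separate measures in this comparison. With only the 20000 strongest peaks of the replicated list, the secreted list (51.4%), the factor list (45.8%) and the globin list (70%) did not pass the threshold. Fewer genes of any kind have a peak at this cut, so these shares are not to be set against the 48.2% of all coding genes.

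Genes of mature liver metabolism were divided. The urea cycle and amino acid list, with enzymes that detoxify ammonia and make glucose, had 17 of 25 promoters with a peak (68.0%, adjusted p = 0.0998, Fisher's exact test). Glul, for glutamine synthetase, was its strongest member with 32.1 ± 1.26 (chromosome 1, peak 153899069 to 153901761), ahead of Asl (15.6 ± 0.688) and Oat (14.5 ± 5.23). G6pc and Sds had no promoter peak, though 1812 bp were covered within 5 kb of the TSS at G6pc (0 bp at Sds). Adult P450, bile acid and conjugation genes had 11 of 26 (42.3%, adjusted p = 0.617, Fisher's exact test), led by Fmo5 (11.8 ± 1.16), Cyp3a11 (6.38 ± 0.132) and the bile salt exporter Abcb11 (5.87 ± 0.891). Cyp1a2 and Cyp2a5 had none, and 62.6% of the words at Cyp2a5 had another copy. Against genes of like promoter GC content, both lists stood above the background. The share of P450 genes was then 42.3% against 18.9% (adjusted p = 0.00767, permutation test) and that of urea cycle genes 68.0% against 47.2% (adjusted p = 0.0378, permutation test). The direction for P450 genes thus depended on the background.

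**Figure D2:**
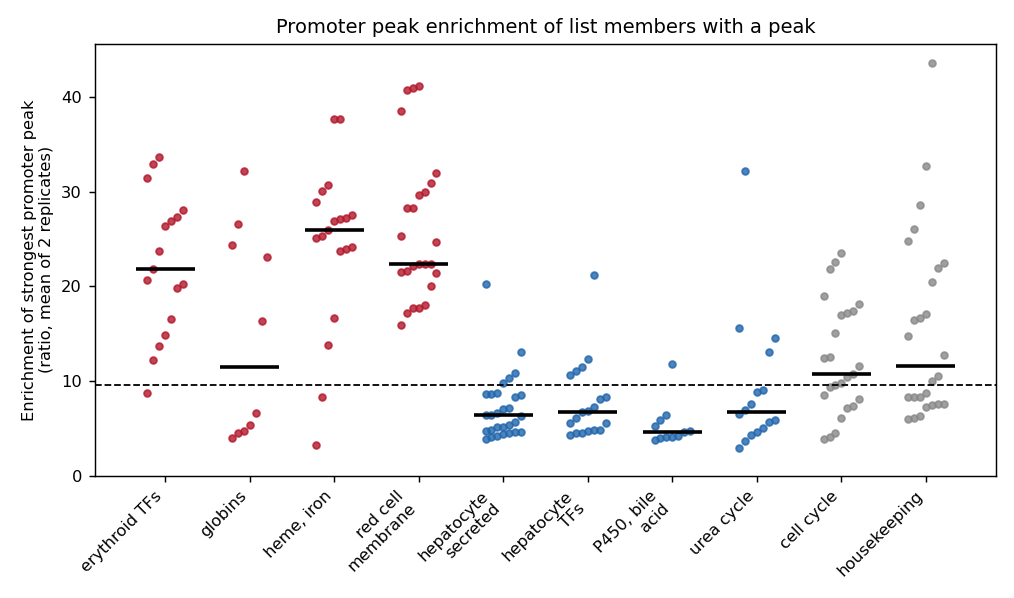
Enrichment ratio of the strongest promoter peak, mean of 2 replicates (y axis), for each gene with a peak (points) in 10 of the 23 lists (x axis), with list medians as bars and the median of all coding genes with a peak (9.61) as a dashed line. The erythroid factor, heme and red cell membrane medians lie at 21.8, 25.9 and 22.3, the globin median at 11.5, and the hepatocyte secreted and factor medians at 6.38 and 6.78.

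Among white blood cell and progenitor lists, only the lymphoid list differed from other genes in the main comparison, and it lay below them. Haematopoietic stem and progenitor genes had a peak at 12 of 24 promoters (50%, adjusted p = 1, Fisher's exact test). Mllt3, a stem cell maintenance gene, had 35.4 ± 0.486 at an internal TSS (chromosome 4, peak 87805953 to 87807470), Lyl1 28 ± 5.12 and Etv6 13.8 ± 3.09, whereas Cd27 and Cd34 had none. Granulocyte and monocyte genes had 15 of 22 (68.2%, adjusted p = 0.116, Fisher's exact test) with low enrichments, the highest being 6.37 ± 1.2 at Cebpe, 6.26 ± 0.369 at Tyrobp and 4.59 ± 1.52 at Csf3r. This list passed the threshold against genes of like GC content (68.2% against 37.1%, adjusted p = 0.00296, permutation test) and in each replicate alone (77.3%). Its members Ccr2 and Ly6c2 had no peak, and 57.6% of the words at Ly6c2 had another copy. Megakaryocyte genes had 9 of 20 (45%, adjusted p = 0.864, Fisher's exact test), led by the platelet receptor genes Gp9 (13.7 ± 1.11) and Gp1ba (10.2 ± 0.847) and by Nbeal2 (5.76 ± 1.34), with none at Gp1bb and Gp6. Kupffer cell and macrophage genes had 7 of 20 (35.0%, adjusted p = 0.310, Fisher's exact test), with the iron exporter gene Slc40a1 at 15.9 ± 2.61, Id3 at 6.37 ± 1.24, Nr1h3 at 6.11 ± 2.07, and none at Axl and C1qa. Only 1 of 22 lymphoid genes had a peak (4.55%, adjusted p = 3.14e-05, Fisher's exact test), Lck at 8.09 ± 1.43, at an internal TSS, while Bcl11b and Blk had none.

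Lists of supporting cells of the liver had fewer replicated promoter peaks than other genes, but these results depended on the peak list or did not pass the threshold. Stellate and mesenchymal genes had a peak at 3 of 26 promoters (11.5%, adjusted p = 2.10e-04, Fisher's exact test), namely Reln (15.5 ± 5.78), Vim (7.20 ± 0.233) and Hgf (3.8 ± 0.282). Col1a2 and Col3a1, the fibrillar collagen genes, had none. In replicate 2 alone, 30.8% of this list had a peak and the difference no longer passed the threshold (adjusted p = 0.0646, Fisher's exact test). Endothelial genes had 7 of 27 (25.9%, adjusted p = 0.0324, Fisher's exact test), led by Maf (6.05 ± 0.793), Pecam1 (5.86 ± 0.0995) and Eng (4.84 ± 0.566), with none at Clec4g and Esam. This call was not kept in replicate 1 alone (44.4%) or replicate 2 alone (51.9%), where 51.5% of all genes had a peak in each. Cholangiocyte genes had 7 of 21 (33.3%, adjusted p = 0.236, Fisher's exact test), with Hnf1b at 9.22 ± 1.83 (at an internal TSS), Krt18 at 8.58 ± 1.21 and Sox4 at 7.56 ± 0.777, and none at Cdh1 and Cftr. Within 5 kb of the TSS, 1178 bp were covered at Cdh1 (0 bp at Cftr).

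Dividing and housekeeping programmes were fully acetylated, and those of other organs nearly absent. All 25 cell cycle genes had a promoter peak (adjusted p = 9.01e-08, Fisher's exact test), led by Kif11 (23.6 ± 1.05), Mcm7 (22.6 ± 4.88) and Rrm1 (21.8 ± 1.83). All 26 housekeeping genes had one (adjusted p = 9.01e-08, Fisher's exact test), led by Actb (43.5 ± 6.18), Vcp (32.6 ± 3.08) and Snrpd3 (28.6 ± 0.359). Fetal growth and imprinted genes had 13 of 20 (65.0%, adjusted p = 0.228, Fisher's exact test). Igf2bp3, an RNA-binding protein of fetal tissues, had 21.2 ± 1.93, Igf1r 13.1 ± 0.238 and Plag1 10.5 ± 1.58, and Lin28a and Plagl1 had none. This list passed the threshold in each replicate alone (85% and 80%). Hox genes, which pattern the body axis, had 3 of 39 (7.69%, adjusted p = 6.25e-07, Fisher's exact test), namely Hoxa1 (4.24 ± 0.85), Hoxb4 (4.23 ± 0.384) and Hoxb2 (3.81 ± 0.565), with none at Hoxa10 and Hoxa11. The neuron, muscle and other-epithelium lists had 1 of 27 each (3.70%, adjusted p = 1.91e-06, Fisher's exact test). These were Map2 (6.81 ± 0.713, at an internal TSS), Tnni2 (6.39 ± 0.972, at an internal TSS) and Cela1 (5.65 ± 0.645, at an internal TSS). Ascl1, Dcx, Acta1, Actc1, Amy2a5 and Barx1 had none, and all words at Amy2a5 (100%) had another copy.

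**Figure D3:**
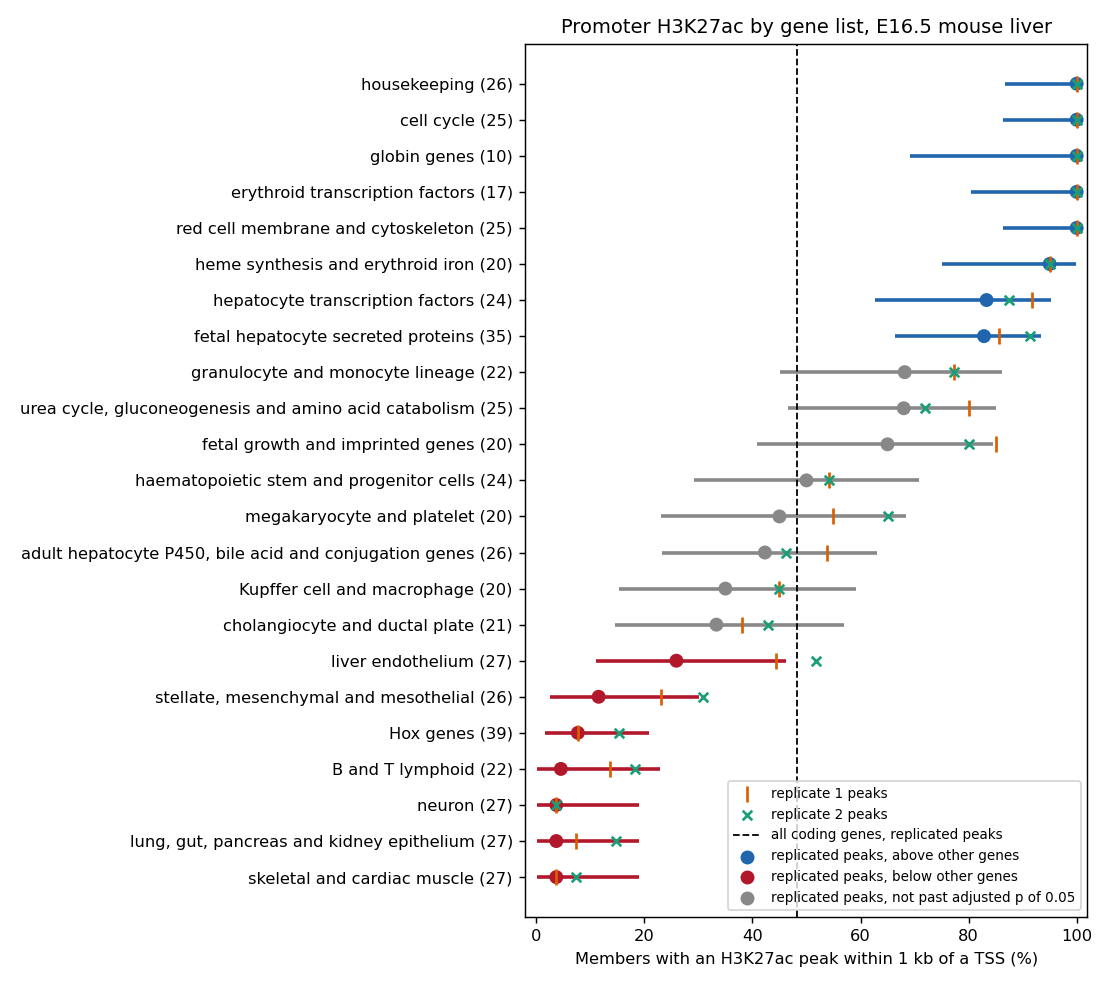
Percent of the members of each gene list with an H3K27ac peak within 1 kb of a TSS (x axis), for 23 lists with their size in brackets (y axis), as circles with 95% Clopper-Pearson intervals for the replicated peaks and as marks for each replicate. The dashed line is the 48.2% of all coding genes, and colours give the side and outcome of Fisher's exact test at an adjusted p of 0.05.

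Acetylation around red cell promoters was broad. Breadth was measured as the bases covered by replicated peaks within 5 kb of the TSS, for list members with a promoter peak, against 10000 random lists of such genes. The median was 7042 bp for erythroid transcription factors, 6404 bp for heme and iron genes and 5716 bp for red cell membrane genes, against 1590 bp for all coding genes with a promoter peak. Each had a permutation p of 2.00e-04, the smallest that 10000 lists can give (adjusted p = 0.00127 over 19 lists, permutation test). Nfe2 had 9807 bp covered, Cpox 8931 bp and Zbtb7a 8135 bp, at least the 99.6th percentile of all genes. The globin median was 4306.5 bp (adjusted p = 0.00285, permutation test) and the housekeeping median 2722.5 bp (adjusted p = 0.0152, permutation test). Hepatocyte secreted genes (2119 bp, adjusted p = 0.187, permutation test), hepatocyte factors (2287 bp, adjusted p = 0.174, permutation test) and cell cycle genes (2279 bp, adjusted p = 0.134, permutation test) did not pass the threshold. The cell cycle list did in each replicate alone (3307 and 2651 bp), the secreted list in replicate 1 alone (2563.5 bp) and the factor list in replicate 2 alone (2760 bp). P450 and bile acid genes had fewer bases covered, with a median of 705 bp (adjusted p = 0.0355, permutation test), but not against genes of like GC content (adjusted p = 0.230, permutation test). The other 10 lists did not pass the threshold, with adjusted p from 0.104 to 0.694 (permutation test). In each replicate alone, endothelial genes (582.5 and 497.5 bp) and stellate genes (579 and 586 bp) did, with fewer bases covered than random lists.

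The largest acetylated region was at the alpha-globin genes. Replicated peaks at most 10 kb apart were joined into 16321 clusters and ranked by the bases they covered. The 500 top clusters each covered at least 10.3 kb and together held 23.6% of all covered bases. The first held the alpha-globin genes and Nprl3, on chromosome 11 from 32216487 to 32300994, where peaks covered 57.8 kb (60.4 ± 0.0658 kb in the replicate lists, SD, n = 2). Cd24a on chromosome 10 followed with 52.7 kb (56.0 ± 3.73 kb), then Zfpm1, the GATA1 cofactor gene, on chromosome 8 with 51.8 kb (52.0 ± 1.11 kb). The next were a cluster with Cdk5rap3, Pnpo, Prr15l and Sp2 (48.8 kb), 1 with Emilin2 and Lpin2 (47.6 kb), and a histone gene cluster on chromosome 13 (45.9 kb). They were followed by the cluster of Stk11, Cirbp, Midn, Sbno2, Atp5d, Cbarp and 1600002K03Rik (44.2 kb), that of Hemgn, Anp32b and Trmo (42.6 kb), Cpeb4 (41.2 kb) and Hipk2 with Tbxas1 (40.7 kb). Ranks 11 to 20 covered 34 to 39.8 kb. They held Birc5 with Tk1 and 6 neighbours, Bmp2k, Lpcat1, Ptpn11 with Hectd4 and Rpl6, Bcl2l1, Mtss1, Zfp36l2, Eef2k and Btg2 with Chit1, and 1 cluster without a coding TSS whose nearest gene was Eed. The last 5 were Epb41 with Gm10300 (33.7 kb), Ank1 (33.4 kb), the beta-globin genes on chromosome 7 from 103806792 to 103878691 (32.8 kb, 34.7 ± 1.76 kb in the replicate lists), March3 (32.6 kb) and Foxo3 (32.5 kb). Of these 25 clusters, 7 held a gene of the 4 erythroid lists and 17 held no gene of any list.

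**Figure D4:**
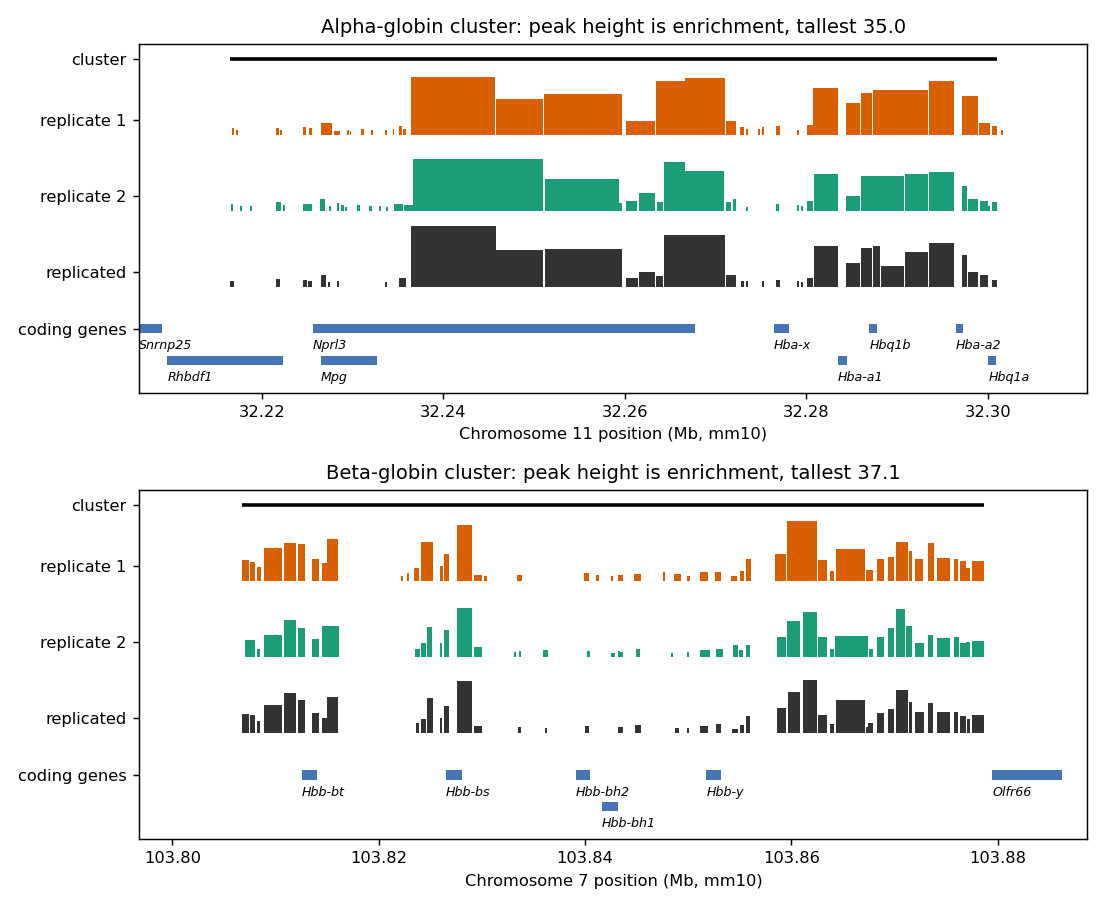
Peaks at the alpha-globin locus on chromosome 11 and the beta-globin locus on chromosome 7 (x axes, position in Mb on mm10), drawn as boxes whose height is the enrichment ratio, for replicate 1, replicate 2 and the replicated list, with the joined cluster as a line and coding genes below. The clusters run from 32216487 to 32300994 and from 103806792 to 103878691, and the tallest boxes at the alpha-globin locus lie over Nprl3.

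Red cell lists were overrepresented at the 500 top clusters, which held a TSS of 937 coding genes (4.29%). Of the erythroid factors, 13 of 17 had a TSS inside one (76.5%, adjusted p = 7.24e-14, Fisher's exact test). So did 13 of 20 heme and iron genes (65.0%, adjusted p = 6.97e-13, Fisher's exact test), 10 of 25 red cell membrane genes (40%, adjusted p = 2.12e-07, Fisher's exact test) and all 10 globin genes, which share 2 clusters (adjusted p = 2.33e-13, Fisher's exact test). Of the 35 secreted hepatocyte genes and the 24 hepatocyte factors, 1 each did (adjusted p = 1, Fisher's exact test). Cell cycle genes had 5 of 25 (20.0%, adjusted p = 0.0172, Fisher's exact test), but this call was lost in each replicate alone (12.0%), with gaps of 20 kb (16%) and when clusters were ranked by signal (12.0%). Housekeeping genes had 4 of 26 (15.4%, adjusted p = 0.0911, Fisher's exact test) and passed the threshold in each replicate alone (23.1%). The other 15 lists had at most 3 members at a top cluster, with adjusted p from 0.171 to 1 (Fisher's exact test).

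Distal peaks carried motifs of red cell and of liver factors, but motifs outside these groups were raised as well. Windows of 500 bp at the centres of 35884 distal peaks were compared with control windows matched on chromosome and GC content (47.7%). The combined motif of TAL1 and GATA1, which bind together at red cell enhancers, was present in 2.55% of peaks and 1.10% of controls (2.31-fold, adjusted p = 1.22e-47, Fisher's exact test over 20 motifs). The GATA motif alone was present in 9.56% and 6.03% (1.59-fold, adjusted p = 5.12e-69, Fisher's exact test). Of the hepatocyte factors, HNF1 showed 0.571% and 0.273% (2.09-fold, adjusted p = 1.08e-09, Fisher's exact test), HNF4A 2.15% and 1.35% (1.60-fold, adjusted p = 5.46e-16, Fisher's exact test) and FOXA 14.2% and 11.4% (1.24-fold, adjusted p = 4.09e-28, Fisher's exact test). The motif of KLF1, another erythroid factor, was 1.15-fold higher in peaks (adjusted p = 7.85e-17, Fisher's exact test). A match to a consensus does not show which factor of a family binds, and the hepatocyte factor list itself holds Gata4 and Gata6. Outside the red cell and hepatocyte groups, MEF2 was 1.84-fold, RUNX 1.41-fold and PU.1 1.32-fold higher (adjusted p from 3.35e-28 to 5.46e-12, Fisher's exact test). The ratio of MEF2 was above those of GATA alone, HNF4A and FOXA. Written backwards, these motifs ranged from 0.766-fold (PU.1) and 0.833-fold (GATA) to 1.19-fold (HNF4A). Each differed from its backwards form in the ratio of hits in peaks to hits in controls (adjusted p from 3.89e-51 to 0.00539, Fisher's exact test over 19 motifs, chosen after the values were seen).

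For NFE2, CEBP, OCT and the E-box of MYOD the backwards form was not a control of like composition. Written backwards, each gains a CG pair that its consensus lacks. Peak windows held more CG pairs than controls (1.29 against 1.21 per 100 bp). The comparisons with the backwards form therefore decided nothing for these motifs. NFE2 was 1.96-fold higher in peaks (372 and 190 windows, adjusted p = 2.35e-14, Fisher's exact test). Its backwards form was 1.92-fold higher but rare (23 and 12 windows), too few to separate the forms (adjusted p = 1, Fisher's exact test). CEBP was 1.08-fold higher (adjusted p = 4.24e-07, Fisher's exact test), less than its backwards form at 1.29-fold (adjusted p = 6.75e-06 for the difference, Fisher's exact test). OCT was less frequent in peaks than in controls at 0.751-fold (adjusted p = 5.95e-14, Fisher's exact test), with 0.777-fold for its backwards form (adjusted p = 0.869 for the difference, Fisher's exact test). The E-box of MYOD was 1.16-fold and GRHL 1.18-fold higher, and TEAD was at 0.865-fold and SOX at 0.876-fold (adjusted p from 1.97e-23 to 1.48e-05, Fisher's exact test). GRHL and the E-box of MYOD were thus raised no less than KLF1 (1.15-fold). Backwards, GRHL was at 0.970-fold, TEAD at 1.03-fold and SOX at 1.13-fold, each different from the motif itself (adjusted p from 1.27e-08 to 1.95e-04, Fisher's exact test). For the E-box of MYOD, at 0.943-fold backwards, the difference did not pass the threshold (adjusted p = 0.0593, Fisher's exact test). CTCF (0.980-fold), REST (0.879-fold), RFX (0.741-fold) and NRF1 (1.41-fold) did not pass the threshold (adjusted p from 0.0569 to 0.908, Fisher's exact test). Against sequences drawn from dinucleotide frequencies, CEBP (0.713-fold), GRHL (0.739-fold), OCT (1.12-fold) and TEAD (1.15-fold) turned to the other direction, so these 4 depended on the control chosen.

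**Figure D5:**
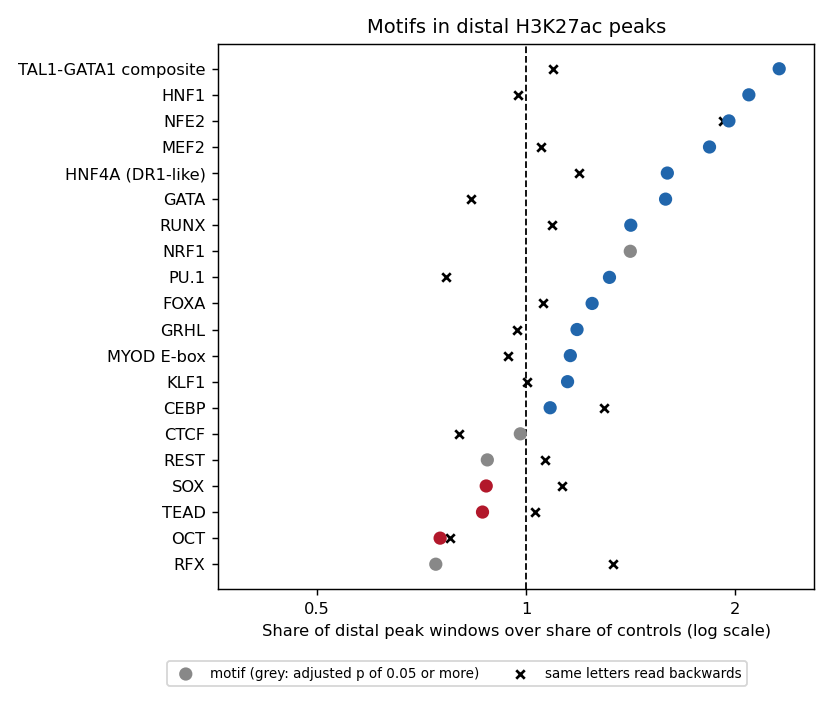
Share of distal peak windows with a motif over the share of control windows (x axis, log scale) for 20 motifs (y axis), as circles coloured by direction where Fisher's exact test passed an adjusted p of 0.05, with crosses for the same letters read backwards. The combined TAL1 and GATA1 motif stands highest at 2.31, and the NFE2 and OCT circles lie next to their crosses.

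No gene list separated the replicates in promoter enrichment. Across genes, promoter enrichment correlated between replicates with a Spearman rho of 0.935, and the median log2 ratio of replicate 1 over replicate 2 was 0.16 (SD 0.35). The median log2 ratio was 0.16 for erythroid factors, 0.29 for red cell membrane genes, 0.05 for secreted hepatocyte genes and −0.16 for granulocyte genes. None of the 19 lists with at least 3 members lay outside the central 95% of random lists of like enrichment (percentiles 5.67 to 91.1). This count was 3 when enrichment was summed over bases and 1 with the −log10 p column. The largest single ratios toward replicate 1 were at Gm11037 (6.89-fold), Ptpn6 (4.08-fold), Acbd5 (3.77-fold), Os9 (3.51-fold) and the Y-linked gene Ddx3y (3.41-fold). Toward replicate 2 they were at Sema4d (4.78-fold, at an internal TSS), Gfi1b (2.87-fold), Ccdc134 (2.57-fold), Kif14 (2.53-fold) and Pram1 (2.51-fold). When replicate peaks within 1 kb of the replicated peak were counted, only Acbd5, Ddx3y and Ccdc134 kept a log2 ratio above 1 in size.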

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

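The 2 tests in this part were written down before their values were seen. A strong peak appeared in sequence that the comparisons did not use, an unlocalised contig of chromosome 4. It ran from 15492 to 17476 of the contig (1985 bp) in the pooled and replicated lists. Its enrichment was 53.8 in replicate 1 and 45.7 in replicate 2, and it would have ranked 32 among the 52389 replicated peaks on the main chromosomes.

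Several copies of the contig sequence in the assembly could have collected reads from elsewhere. Only 4.81% of the 1953 words of 32 bases in the peak had another exact copy, which argues against that explanation. Copies in the animals that the assembly lacks were not tested and stay open. The peak suggests an active promoter of a gene on the contig. The TSS at position 15881 of Dhrsx, a dehydrogenase gene, lay inside it (distance 0 bp), where 5 of the 8 exons annotated by GENCODE on the contig matched those of the other annotation. This remains a hypothesis, since no group without the mark was measured.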

How the results depend on the processing

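The alternatives with mostly single-copy promoters, with breadth in place of enrichment for the erythroid and hepatocyte comparison, and without the globin genes were chosen after the results were seen. For the differences below, the cause was not tested, except where the construction of the alternative is named. No paired analysis was possible because there was only 1 group, and 2 pools limit every statement about replicates. The unknown depth left open how many weaker peaks the lists miss.

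Promoter results by list kept their direction and side of the threshold in 200 of 230 cases (7 weaker, 10 stronger, 13 reversed), with no change at promoter widths of 500 bp or q-values of 0.01 or lower. Red cell membrane, heme, erythroid factor, cell cycle and housekeeping lists passed the threshold under all 10 alternatives. Within 2500 bp of a TSS the shares were 80% for urea cycle genes (now past), 50% for megakaryocyte genes (reversed) and 33.3% for endothelial genes (no longer past). In the pooled list they were 72.0% for urea cycle genes (now past) and 50% for megakaryocyte genes (reversed). With the 20000 strongest peaks of the replicated list, 5 lists in place of 8 stood above other genes. Secreted hepatocyte genes (51.4%), hepatocyte factors (45.8%) and globin genes (70%) were no longer past, P450 genes (15.4%) were below, and granulocyte (13.6%) and stem and progenitor genes (33.3%) reversed. With 1 TSS per gene, stem and progenitor genes reversed (45.8%) and endothelial genes were no longer past (25.9%). Against genes of like GC content the shares stayed as they were by construction. P450 genes (42.3%), stem and progenitor genes (50%) and megakaryocyte genes (45%) then lay on the other side of the background, and urea cycle (68.0%) and granulocyte genes (68.2%) passed. With mostly single-copy promoters, stem and progenitor genes (50%) lay below the higher background. In each replicate alone, the ranges were 72.0% to 80% for urea cycle, 77.3% to 77.3% for granulocyte, 80% to 85% for fetal growth, 46.2% to 53.8% for P450, 55.0% to 65.0% for megakaryocyte, 44.4% to 51.9% for endothelial and 23.1% to 30.8% for stellate genes.

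Breadth kept its call in 55 of 76 cases (2 weaker, 10 stronger, 9 reversed). Within 10 kb the medians were 3503 bp for hepatocyte factors and 3185 bp for cell cycle genes (both now past), 1152 bp for P450 genes (no longer past, leaving 0 lists below), and 3040, 2284 and 1871 bp for Kupffer, megakaryocyte and fetal growth genes (reversed). Against like GC content, P450 genes (705 bp) were no longer past, leaving 0 lists below, and endothelial genes (1369 bp) reversed. In each replicate alone the ranges were 2273.5 to 2563.5 bp for secreted hepatocyte genes, 2583.5 to 2760 bp for hepatocyte factors, 1671 to 2040 bp for urea cycle, 546 to 1799 bp for megakaryocyte, 497.5 to 582.5 bp for endothelial, 579 to 586 bp for stellate, 2651 to 3307 bp for cell cycle, 1627 to 1749.5 bp for fetal growth and 582 to 1114 bp for Hox genes. Between 3 and 6 lists were then below.

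The 500 top clusters held 19.3% of covered bases with gaps of 5 kb, 29.7% with 20 kb, 21.7% when ranked by signal, and 22.8% to 23.5% in each replicate alone. Of the 25 top clusters, 12, 14 and 15 stayed among the 25, and 16 to 17 in each replicate alone. List results at clusters held in 100 of 115 cases (4 weaker, 4 stronger, 7 reversed). With gaps of 5 kb, hepatocyte factors reversed (8.33%). With 20 kb, hepatocyte factors (8.33%), urea cycle (8%) and granulocyte genes (13.6%) reversed, cell cycle genes (16%) were no longer past and housekeeping genes (30.8%) passed. Ranked by signal, cell cycle genes (12.0%) were no longer past and housekeeping genes (23.1%) passed. Each replicate alone gave 12.0% to 12.0% for cell cycle, 23.1% to 23.1% for housekeeping, 2.86% to 11.4% for secreted hepatocyte genes, 0% to 9.09% for granulocyte genes and 0% to 8.33% for hepatocyte factors.

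Motif results held in 88 of 100 cases (2 stronger, 10 reversed). CTCF, near 1-fold, reversed with 1000 bp windows (1.33), at over 5 kb from any TSS (1.03) and in each replicate alone (1.03 to 1.15). Against sequences drawn from dinucleotide frequencies, CEBP (0.713), GRHL (0.739), OCT (1.12), TEAD (1.15), RFX (1.78) and CTCF (1.79) reversed, and REST (0.752) and NRF1 (12-fold) passed the threshold.

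Peak overlap moved with its definition. Replicate 1 peaks overlapped in 44.6% when 50% of both peaks had to be shared, 59.5% by centres, 65.8% at q-values of 0.01 or lower and 79.7% for the 20000 strongest. For replicate 2 peaks these were 45.2%, 64.8%, 74.1% and 83.6%. Spearman's rho was 0.738 with the −log10 p column, 0.814 with 50% overlap and 0.733 at q-values of 0.01 or lower. Pooled peaks found in both replicates were 65.2% with 50% overlap and 83.6% at q-values of 0.01 or lower, where 96.6% were kept. The location shares moved by construction with promoter widths of 500 bp, 2500 bp and counting of bases. They were 20.8%, 36.9% and 33.0% for promoters, 5.97%, 4.00% and 4.77% for exons, 50.9%, 40.5% and 43.5% for introns and 22.4%, 18.7% and 18.7% for intergenic sequence. In each replicate alone they were 20.7% to 21.5%, 5.440% to 5.444%, 50.9% to 51.8% and 22.05% to 22.10%.

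Replicate differences by list, with the count of lists outside the random range, shifted by less than the spread of random lists in 24 of 60 cases and by more in 36. With the −log10 p column, 1 list lay outside the random range, and the log2 medians that moved were 0.14 (secreted hepatocyte), 0.16 (urea cycle), 0.33 (erythroid factors), 0.47 (globins), 0.39 (heme), 0.39 (red cell membrane), −0.38 (Kupffer), 0.32 (megakaryocyte), 0.25 (cell cycle) and 0.32 (housekeeping). Summed over bases, 3 lists lay outside, and the medians were −0.035 (P450), 0.15 (urea cycle), 0.38 (erythroid factors), 0.64 (globins), 0.42 (heme), 0.49 (red cell membrane), −0.17 (stem and progenitor), −0.42 (granulocyte), −0.22 (endothelial), −0.39 (stellate), 0.49 (cell cycle), 0.28 (housekeeping) and 0.94 (Hox). Quantile normalization, which removes the shared offset by construction, left 0 lists outside, with −0.14 (hepatocyte factors), −0.16 (urea cycle), −0.049 (erythroid factors), 0.15 (globins), 0.061 (heme), 0.084 (red cell membrane), −0.18 (stem and progenitor), 0.015 (megakaryocyte), 0.010 (cell cycle), −0.096 (fetal growth) and 0.011 (housekeeping).

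The ratio of erythroid to hepatocyte promoter enrichment, 3.92, was 4.05 without the globin genes and 3.43 when measured as covered bases within 5 kb.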

Other observations

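The grouping of erythroid and hepatocyte lists, the comparison of their promoter enrichment, the tests of peak borders and the test at Xist were chosen after the results were seen. Within the globin loci, promoter enrichment varied widely among genes. Hbb-bs had a promoter enrichment of 32.2 ± 3.30 and Hbb-bt 16.4 ± 4.02 (mean ± SD, n = 2), while the embryonic genes of the same locus had 5.39 ± 0.705 (Hbb-y), 3.97 ± 0.238 (Hbb-bh1) and 4.46 ± 1.27 (Hbb-bh2). At the other locus, the embryonic gene Hba-x had 4.70 ± 1.01, against 24.3 ± 4.24 at Hba-a1 and 26.6 ± 6.14 at Hba-a2. The theta-globin genes beside them fell on either side, with 23.1 ± 3.79 at Hbq1b and 6.64 ± 0.861 at Hbq1a, so low values were not confined to embryonic genes. The adult genes are near-identical copies in pairs, so their separate values are uncertain. These genes were picked after their values were seen, and the difference was not tested.

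The albumin gene Alb had a promoter enrichment of only 4.23 ± 0.384. The fetal albumin relative Afp had peaks in both replicates (3.64 ± 0.407) but no replicated promoter peak. Its surroundings were acetylated, with 1898 bp covered within 5 kb of the TSS.

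Erythroid genes may carry more acetylation in their surroundings than hepatocyte genes in this tissue. Their median promoter enrichment was higher by 17.8 (23.9 against 6.10), but this restates the list medians from which the groups were formed and is no test. A test of the bases covered 1 to 50 kb from the TSS was written down before its value was seen. The bases covered within 5 kb and the top clusters of each list were known by then, and both overlap this window. The outcome was therefore largely foreseeable, and the test adds little to those results. The window also counted peaks at promoters of neighbouring genes. The median was 14871 bp for 72 erythroid genes and 3159.5 bp for 110 hepatocyte genes, a difference of 11712 bp (p = 1.00e-05, two-sided permutation test, the smallest that 100000 permutations can give), and 12623 bp without the globin genes. All coding genes had 1232 bp. Unlike the enrichment comparison, these medians include genes without a promoter peak. Of the 72 erythroid genes 71 had a promoter peak, against 77 of the 110 hepatocyte genes. Some of the erythroid genes are neighbours and share peaks. Whether the difference follows from the number of cells of each kind or from the mark in each cell was not tested, since the lists describe whole tissue.

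Motifs near the same genes might differ in the same way, but the evidence was weak. The combined TAL1 and GATA1 motif occurred in 3.23% of 775 distal windows near erythroid genes and 1.31% of 610 near hepatocyte genes, a difference of 1.91 points (p = 0.0211, Fisher's exact test). HNF1 occurred in 0 and 5 windows, a difference of −0.820 points (p = 0.0164, Fisher's exact test). Both met the criterion set in advance and neither passed adjustment over the 20 motifs (adjusted p = 0.211 for each, Fisher's exact test). TEAD, of neither group, also had p under 0.05, being less frequent near erythroid genes (14.8% and 19.0%, p = 0.0421, adjusted p = 0.258, Fisher's exact test). Other motifs of erythroid and hepatocyte factors did not reach p under 0.05. CEBP was less frequent near erythroid genes (16.8% and 21.0%, p = 0.0515, Fisher's exact test), and GATA alone was more frequent there (10.5% and 8.52%, p = 0.234, Fisher's exact test). KLF1 (19.6% and 20.7%), NFE2 (0.774% and 1.15%) and FOXA (13.8% and 12.8%) ran the other way (p from 0.578 to 0.637, Fisher's exact test). For HNF4A the difference of −0.325 points (p = 0.699, Fisher's exact test) decided nothing, and a difference cannot be told apart from none with 14 and 13 windows.

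The missing promoter peak at Slc25a37 may reflect reads shared with another copy of the sequence. All promoter words (100%) had another exact copy, and the TSS lay in a stretch of chromosome 14 without peaks, 453 kb from 69254193 to 69707017. The gene runs from 69241848 to 69285112, so the last peak before the stretch ended inside the gene. The stretch held the TSS of 7 coding genes, of which the lowest had 98.0% of words copied. Across all genes, promoters with at least 90% of words copied had a peak in 0.506% of cases (4 of 791), against 54.8% of those with under 10%. A promoter without H3K27ac in this tissue cannot be told apart from this, because such promoters almost never received a peak whatever their gene. How reads with several matches were treated was not stated.

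Peak borders that differ between replicates could explain most of the largest replicate ratios. When replicate peaks within 1 kb of the replicated peak were counted, 7 of the 10 promoters fell below a log2 ratio of 1 in size, short of the 8 set as the mark, so for the 10 as a set this stays open. Sema4d, for example, went from −2.26 to 0.26. Acbd5, Ddx3y and Ccdc134 did not move, the smallest of their ratios staying at 1.36 in size on the log2 scale (−1.36 at Ccdc134). These 3 were picked because they stayed above 1 in this same count, and signal farther than 1 kb away was not examined. The count therefore decides nothing about borders for them. A larger share of male embryos in replicate 1 would raise Ddx3y on chromosome Y (13.5 against 3.96) and lower Xist on chromosome X. The other replicated peak on chromosome Y was also higher in replicate 1, by less (6.31 against 4.27, log2 0.56). The median log2 ratio at the 3 Xist peaks was 0.37 (SD 0.31), against 0.16 for all promoters, so Xist was not lower. A shift of this size cannot be told apart from none, and a change from a low male share would move Xist little, so the explanation stays open for Ddx3y. Peak borders, chance differences at single peaks and other differences between the pools stay open for Acbd5, Ddx3y and Ccdc134.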
